A study of Mus musculus with 8 samples.

How the data were processed

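The samples were whole pituitary glands of 8 C57BL/6N mice aged 5 weeks, 4 treated with an antibody against CD115 and 4 with a rat IgG2a isotype control. Each group held 1 female (replicate 1) and 3 males (replicates 2 to 4). CD115 is the receptor for colony stimulating factor 1, encoded by Csf1r, and the antibody AFS98 is used to deplete macrophages that depend on it. Per the labels' protocols, a pregnant dam received 3 mg at embryonic day 6.5, and the offspring received 100 µg at postnatal day 2, 150 µg at postnatal day 14 and 200 µg at 4 weeks of age. Libraries were made from 100 ng of RNA with a stranded mRNA kit, per the labels. The labels do not give the number of dams or litters, so litter and treatment may coincide, and no test here can part them.

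Per the submitters' processing notes, the authors used HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 with the mouse build GRCm38; the notes do not give the settings of these tools. The deposited count table holds whole-number counts of reads per gene, without normalisation, for 54854 genes. It includes 322 assembled loci without an Ensembl identifier. The deposited FPKM table gives the same genes with the library size and gene length divided out. Dividing the counts by the listed gene length and by the FPKM values gave 1 constant size per library, which lay between 5.37% below (-5.37%) and 5.98% above the library's total count. In all, 54409 gene identifiers were found in GENCODE M21, and symbols and coordinates were taken from the count table as deposited. Whether counting used the strand is not stated, so reads of overlapping or antisense genes cannot be assigned with certainty. Nor is the treatment of reads shared between near-identical genes stated, which leaves values of multigene families such as the H2, Ms4a, Siglec and Serpina3 genes uncertain to that extent.

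Total counts per library ran from 23289819 to 36218096, so that 3 counts, the floor used where a gene had no read, were worth between 0.0828 and 0.129 CPM (counts per 1e6 counts) in a library. Floors and counting intervals cover counting error only. No library was left out of the main comparison. Pearson correlations of log2 CPM across genes between replicates of a group were 0.971 to 0.989 for genes with a mean above 1 CPM; genes are not independent replicates. Chi-square per degree of freedom between replicates was 15.6 or more, so no library was a technical duplicate of another.

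Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr on treatment, library sizes were scaled with TMM factors, and the quasi-likelihood test was fitted to all 8 libraries with terms for sex and treatment. P-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Standard errors were derived from the F statistic of the test. Levels are TMM-normalised CPM. The same model gave the sex comparison, and a model with a sex by treatment term gave the interaction. With 1 female per treatment group, females were assumed to vary as males do. On simulated counts for 17557 genes of this comparison, the test recovered 10.0% of 50 genes changed 1.25-fold, 33.3% of 48 genes changed 1.5-fold, 75.5% of 49 genes changed 2-fold and 96.0% of 50 genes changed 4-fold, and it called 7 unchanged genes.

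Gene lists, comparisons, the rule for naming genes and the first set of alternatives were fixed before the data were examined. The lists covered macrophage, resident macrophage, microglia, monocyte, dendritic, neutrophil, T and NK cell, B and plasma cell, mast cell and red blood cell markers, and MHC class II antigen presentation genes. They also covered the hormone genes, somatotroph, lactotroph, corticotroph, melanotroph, gonadotroph, thyrotroph, stem and folliculostellate cell, pituicyte, neuron and brain, endothelial, mural and fibroblast, skeletal muscle, and cartilage and bone markers. The remaining lists were cell cycle, immediate early, heat shock, unfolded protein response, interferon, inflammatory, complement, lysosomal, CSF ligand, purinergic, calcium handling, secretory granule, pituitary receptor, pituitary transcription factor, extracellular matrix and mitochondrially encoded genes. All 472 listed members were found in the count table. Lists with at least 3 expressed members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and again with the correlation estimated from the residuals; 39 lists were tested. The fry test of limma gave the direction of a list on its own. In simulated data camera called 0 of 40 unchanged lists and called a list lowered by design. Genes were drawn independently there, so the simulation cannot show how often camera calls unchanged lists whose members vary together. In the real data the estimated correlation was 0.692 for macrophage markers and 0.919 for cell cycle genes. The listed X-inactivation and Y-linked genes served to check the sex labels; they were not left out of the sex comparison and are among the genes it called.

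Genes named for the treatment were Csf1r, the 7 hormone genes, the 5 macrophage and 5 resident macrophage markers with the smallest p, up to 10 rises and 10 falls of the largest size, and 2 to 4 members of each described list with the smallest p. The largest changes were taken among called genes with a mean log2 CPM of at least 1 that moved the same way in the female pair and placed all 3 treated males beyond all 3 control males. Of the called genes, 71 falls and 7 rises met this rule. For sex, the 5 largest changes each way outside X-inactivation and Y-linked genes were named among called genes with a mean log2 CPM of at least 1, and for the interaction the 5 smallest p. Results of some genes that the rule would name are not reported here.

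The alternatives were median-ratio size factors, the Wald test of DESeq2 1.42.0, limma-voom, no filter beyond 1 count in total, a stricter filter of 1 CPM in 4 libraries, no sex term, a replicate block, males only, and each library left out in turn. With 1 female per group, leaving out either female leaves the treatment comparison to the males. For treatment, these fits and males only are thus nearly the same comparison and not separate checks. The deposited FPKM values were also tested with limma on log2(FPKM + 1) and log2(FPKM + 0.1), for genes with a mean of at least 1 FPKM or without that filter; fold changes on that scale understate the change of weakly expressed genes. An alternative without anti-CD115 replicates 1 and 3 was added after the data were seen. The 35 splits of the 8 libraries into 4 and 4 were each fitted with the same model. Samples far from the rest of their group were sought with Dixon's ratio, at a critical value of 0.829.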

Results

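The data comprised transcript counts from 8 mouse pituitaries, 4 after repeated injection of anti-CD115 and 4 after an isotype control antibody, collected 1 week after the last of 4 injections. The control libraries, replicates 1 to 4, held 23590300, 28166824, 34724813 and 30109844 counts, and the anti-CD115 libraries held 27061580, 26984457, 36218096 and 23289819. Growth hormone transcripts took 13.5% to 23.0% of the counts of a library, and the 10 most abundant genes of each library together took 25.1% to 31.5%. Mitochondrially encoded transcripts made up 2.36% to 2.86%. TMM factors lay between 0.939 and 1.05. The Y-linked and X-inactivation transcripts placed every library with its labelled sex. Xist stood at 99.0 and 161 CPM in the control and anti-CD115 female and at no more than 0.714 CPM in any male. Kdm5d and Eif2s3y had no count in either female and were at least 437-fold and 318-fold higher in males, against a floor of 3 counts over both females.

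The first comparison asked what depletion of CSF1R-dependent macrophages changed in the pituitary, and macrophage transcripts served as the check of the treatment. Csf1r, the gene of the antibody's target (ENSMUSG00000024621, chromosome 18, 61105572 to 61132149, GRCm38), fell 8.04-fold, from 32.9 ± 6.86 CPM (SD, n = 4) to 4.18 ± 2.52 CPM (SD, n = 4; edgeR, log2 fold change -3.01, SE 0.37, adjusted p = 0.00294). The treated libraries ranged from 1.43 to 6.80 CPM and the controls from 26.9 to 40.3 CPM. Of the 22 macrophage markers, 18 fell, 0 rose and 4 passed in neither direction; 21 fell when p-values were adjusted over the list alone. The median log2 change of the list was -2.75 (camera adjusted p = 4.19e-112; adjusted p = 0.0274 with an estimated correlation). The strongest tests belonged to Laptm5, a lysosomal membrane protein of leukocytes (log2 -2.56), Spi1, the transcription factor PU.1 of the myeloid lineage (-2.74), the perforin-like Mpeg1 (-2.32), Ly86 (-3.04) and cathepsin S, Ctss (-2.82), all with edgeR adjusted p of 0.000945 or less. The 10 largest falls among all genes that met the naming rule were Cd33 (-3.38), Adgre1, which encodes F4/80 (-3.33), C1qa (-3.27), Aif1 (-3.25), Ms4a7 (-3.14), Ly86 (-3.04), Csf1r (-3.01), Fcrls (-2.99), C1qc (-2.95) and C1qb (-2.93).

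**Figure D1:**
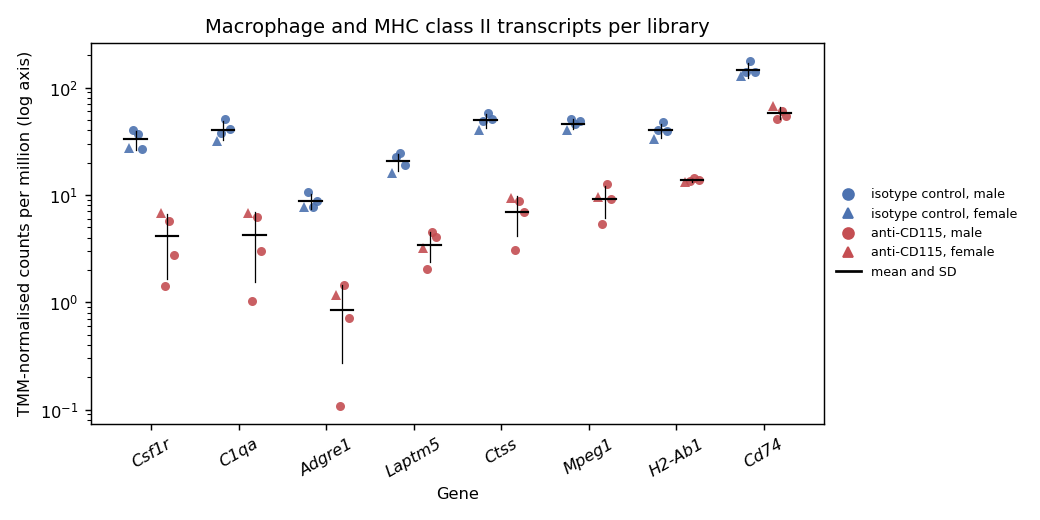
TMM-normalised CPM (log axis) of macrophage and MHC class II transcripts in each library, with isotype control in blue and anti-CD115 in red, males as circles and females as triangles, and the mean and SD of each group of 4 in black. For Csf1r the treated libraries lie between 1.43 and 6.80 CPM and the controls between 26.9 and 40.3 CPM.

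Across the 17723 genes tested, anti-CD115 changed 154, of which 147 fell and 7 rose (edgeR, adjusted p below 0.05), while 1833 had an unadjusted p below 0.05. All 154 moved the same way in the female pair and placed the 3 treated males beyond the 3 control males. Among the fallen genes, 132 fell more than 2-fold, 80 more than 4-fold and 16 more than 8-fold, with a median log2 change of -2.13. In all, 34 of them were on a leukocyte list. Without anti-CD115 replicate 4 the test called 89 genes, of which 87 fell, and without anti-CD115 replicate 2 it called 101, all of them falls. DESeq2 called 268, with 216 falls and 52 rises, and edgeR without the low-count filter called 487, with 353 falls and 134 rises.

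Markers of tissue-resident macrophages fell for 4 of 12 genes measured, with 8 in neither direction and 4 falling when adjusted over the list alone (median log2 -0.38, camera adjusted p = 2.00e-11; adjusted p = 0.111 with an estimated correlation). They were the mannose receptor Mrc1 (-2.60, SE 0.34), Ms4a7 (-3.14, SE 0.42), the lipoprotein Apoe (-0.95, SE 0.16) and Fcrls (-2.99, SE 0.57), whereas F13a1 gave -1.43 with an edgeR adjusted p of 0.388. Of 9 microglia markers, 4 fell and 5 did not pass, with 5 falling when adjusted over the list alone (median log2 -0.65, camera adjusted p = 1.64e-09; adjusted p = 0.111 with an estimated correlation). Siglech (-2.39), Gpr34 (-2.34) and the ADP receptor P2ry12 (-2.32) fell about as far as the macrophage markers. P2ry12 stood at 2.46 CPM in the anti-CD115 female and at 0.357 to 0.528 CPM in the anti-CD115 males, and leaving out the control or the anti-CD115 female gave a log2 change of -3.09. Without anti-CD115 replicate 3 that of Fcrls was -3.67, and without isotype control replicate 3 that of F13a1 was -0.84. The calls of Apoe, Siglech, Fcrls, P2ry12 and Gpr34 each ended without anti-CD115 replicate 4 (adjusted p = 0.0922, 0.0876, 0.0988, 0.103 and 0.0997) and without anti-CD115 replicate 3 (0.0756, 0.0505, 0.0538, 0.122 and 0.0845). They ended, too, without isotype control replicate 2 (0.0665, 0.0678, 0.0922, 0.0720 and 0.106). Those of Fcrls, P2ry12 and Gpr34 also ended without isotype control replicate 3 (0.0835, 0.0649 and 0.0811) or 4 (0.0713, 0.0566 and 0.0901) and without anti-CD115 replicate 2 (0.0831, 0.107 and 0.129). The same held for Apoe without anti-CD115 replicate 2 (0.0902) and Siglech without isotype control replicate 3 (0.0561). Other settings ended calls as well: limma-voom for P2ry12 (0.05005), the stricter filter for Fcrls (0.0508), and log2(FPKM + 0.1) for Apoe (0.0953) and Fcrls (0.106). Log2(FPKM + 1) ended that of Apoe (0.0883). Without a sex term those of Apoe (0.0781), Fcrls (0.0540), P2ry12 (0.186) and Gpr34 (0.0527) ended, and with a replicate block those of Siglech (0.0634), P2ry12 (0.0991) and Gpr34 (0.113). Unfiltered FPKM ended those of Mrc1 (0.120), Apoe (0.199), Fcrls (0.0919), Siglech (0.0612), P2ry12 (0.110) and Gpr34 (0.111).

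Genes of MHC class II antigen presentation fell for 5 of 8 members, with 3 in neither direction and 7 falling when adjusted over the list alone (median log2 -1.44, camera adjusted p = 4.40e-52; adjusted p = 0.0266 with an estimated correlation). H2-Ab1 went from 40.1 ± 6.08 to 13.7 ± 0.460 CPM (SD, n = 4 each; edgeR log2 -1.55, SE 0.10, adjusted p = 0.000229). H2-Aa (-1.60), H2-Eb1 (-1.59) and the invariant chain Cd74 (-1.33) fell to a similar degree, and less than the macrophage markers. Among complement genes, 5 of 10 fell, 5 passed in neither direction, and 5 fell when adjusted over the list alone (median log2 -1.74, camera adjusted p = 2.11e-15; adjusted p = 0.104 with an estimated correlation). These included the C1q chains C1qa, C1qb and C1qc and the receptor C3ar1 (-2.70). Without anti-CD115 replicate 4 the call of C1qc ended (edgeR adjusted p = 0.0643). Log2(FPKM + 0.1) ended the calls of C1qb (0.0527) and C1qc (0.0937), and unfiltered FPKM those of C1qa (0.0536), C1qb (0.0870) and C1qc (0.0789).

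Of 13 lysosomal genes, 1 fell and 12 did not pass; 2 fell when adjusted over the list alone, and all 13 had values below 0 (median log2 -0.17, camera adjusted p = 9.68e-07; adjusted p = 0.269 with an estimated correlation). Lgmn (-0.29) and Gusb (-0.20) did not pass over all genes. Of 12 interferon-stimulated genes, 1 fell, Irf7 (-1.12, edgeR adjusted p = 0.0156), also when adjusted over the list alone, and 11 did not pass, among them Usp18 (-0.34). The list had a median log2 change of -0.25 (camera adjusted p = 1.27e-04; adjusted p = 0.297 with an estimated correlation). Irf7 did not pass without anti-CD115 replicate 3 (adjusted p = 0.0698) or 4 (0.0631). Nor did it with log2(FPKM + 1) (0.0833), log2(FPKM + 0.1) (0.0723) or unfiltered FPKM (0.184). DESeq2 called Lgmn (0.0318). None of the 4 expressed inflammatory genes passed over all genes, 1 fell when adjusted over the list alone, and the list was lower (median log2 -0.60, camera adjusted p = 0.0121; adjusted p = 0.174 with an estimated correlation; 0.0683 without isotype control replicate 3). Interleukin 1 beta, Il1b, was at 0.759 ± 0.202 CPM in controls and 0.0971 ± 0.0969 CPM with anti-CD115 (SD, n = 4 each; log2 -3.03, edgeR adjusted p = 0.0520), Cxcl10 had a log2 change of -1.21 and Ccl2 of 0.17; neither passed. Ccl2 turned sign without isotype control replicate 2 or 3 (-0.04 and -0.03) or anti-CD115 replicate 2 (-0.03). Cxcl10 gave -2.06 without anti-CD115 replicate 3, and Il1b -3.67 without anti-CD115 replicate 4. The inflammatory list did not pass with limma-voom (0.09405), while Il1b passed with DESeq2 (0.00358), without the low-count filter (2.33e-04) and without a sex term (0.0491).

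Markers of T and NK cells were lower as a list (median log2 -0.79, camera adjusted p = 0.00323; adjusted p = 0.269 with an estimated correlation). Of 7 measured, 1 fell and 6 did not pass, while 1 rose and 2 fell when adjusted over the list alone. The granzyme Gzma fell (-1.63, edgeR adjusted p = 0.0417), but it did not pass without isotype control replicate 1, 3 or 4 (0.218, 0.139 and 0.127) or anti-CD115 replicate 1, 2, 3 or 4 (0.193, 0.168, 0.115 and 0.104). Cd4, which mouse macrophages can also carry at low levels, had a log2 change of -1.56 (adjusted p = 0.0520) and Trbc2 of 0.65 (0.323). Gzma did not pass with limma-voom (0.0639), unfiltered FPKM (0.122), a replicate block (0.0770) or males only (0.205), and the T and NK list did not with the stricter filter (0.206). Cd4 passed with DESeq2 (0.00236), limma-voom (0.0431) and without the low-count filter (7.70e-04). Purinergic receptors and ectonucleotidases fell for 3 of 18 members, the receptors P2ry6 (-2.70), P2ry12 (-2.32) and P2ry13 (-2.25), with 15 in neither direction; 1 rose and 4 fell when adjusted over the list alone. P2rx7 had a log2 change of -0.92 (adjusted p = 0.182). It passed with DESeq2 (0.0387) and without the low-count filter (0.0198). For the purinergic list camera and the mean (log2 -0.38) pointed down and the median (0.07) up (camera adjusted p = 0.0458; adjusted p = 0.416 with an estimated correlation). The list did not pass without isotype control replicate 2 or 3 (0.0975 and 0.229) or anti-CD115 replicate 2 or 3 (0.0590 and 0.156). It did not pass with limma-voom (0.285), unfiltered FPKM (0.507) or a replicate block (0.0511), and pointed up with log2(FPKM + 1) (0.223) and log2(FPKM + 0.1) (0.172). P2ry13 did not pass with limma-voom (0.0513), unfiltered FPKM (0.0974), no sex term (0.0570) or a replicate block (0.118). P2ry12 and P2ry13 did not pass in edgeR without isotype control replicate 2 (0.0720 and 0.110), 3 (0.0649 and 0.0891) or 4 (0.0566 and 0.0901), or without anti-CD115 replicate 2 (0.107 and 0.0902), 3 (0.122 and 0.0958) or 4 (0.103 and 0.142).

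The remaining leukocyte lists did not pass as lists. Of 4 dendritic cell markers expressed, Itgax fell (-2.20, edgeR adjusted p = 0.00929), also when adjusted over the list alone, and 3 did not pass, among them the dendritic cell factor Zbtb46 (0.16). The dendritic list had a mean log2 change of -0.47 and a median of 0.07, with camera pointing down (adjusted p = 0.114; adjusted p = 0.359 with an estimated correlation). Of 6 B and plasma cell markers, Ighm fell (-1.36, adjusted p = 0.00522), also when adjusted over the list alone, and 5 did not pass, among them Cd79b (-0.48); the median was 0.02 and the mean -0.18 (camera adjusted p = 0.126, downward; adjusted p = 0.388 with an estimated correlation). Without anti-CD115 replicate 3 Itgax did not pass (edgeR adjusted p = 0.0526), and without isotype control replicate 4 the dendritic list did (camera adjusted p = 0.0467). Itgax did not pass with unfiltered FPKM (0.123). The B and plasma cell list passed downward with the stricter filter (camera adjusted p = 0.00389), log2(FPKM + 1) (0.0294) and log2(FPKM + 0.1) (0.0324). None of 6 monocyte markers passed, although 1 fell when adjusted over the list alone (median log2 -0.18, downward, camera adjusted p = 0.499). None of 6 neutrophil markers passed, and 1 fell when adjusted over the list alone (median 0.09, mean -0.08, downward, camera adjusted p = 0.613). Of the mast cell list only 2 members were expressed, too few for camera, and neither passed. The CSF ligand list had 4 members expressed, none passed, and 1 fell when adjusted over the list alone (median 0.03, mean -0.27, downward, camera adjusted p = 0.547). The neutrophil list pointed up without isotype control replicate 3 (0.470) or anti-CD115 replicate 4 (0.925), and the CSF ligand list without isotype control replicate 3 (0.748).

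**Figure D2:**
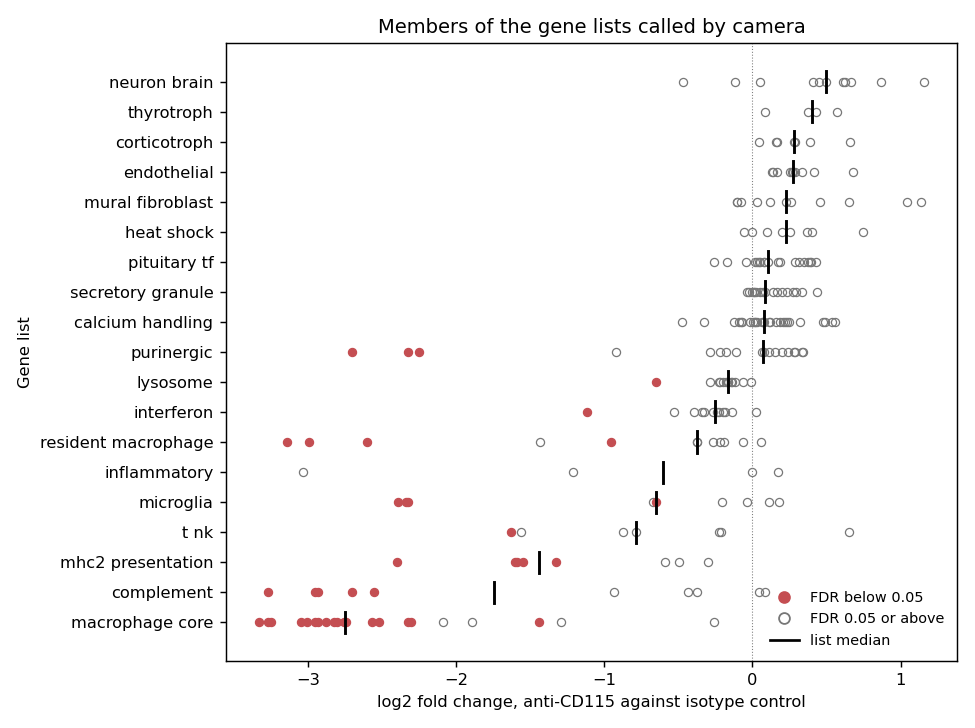
log2 fold change of anti-CD115 against isotype control (horizontal axis) for every expressed member of the 19 gene lists that camera called at a preset correlation, with filled red points for genes at an adjusted p below 0.05, open points for the others and a black bar at the list median. Macrophage markers have a median of -2.75 and MHC class II genes of -1.44; no member of the lists with a median above 0 rose past the threshold.

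The second question was whether hormone gene expression differed after macrophage depletion. None of the 7 pituitary hormone genes passed in edgeR, over all genes or over the list alone, and the smallest adjusted p was 0.345. At an unadjusted p below 0.05 there was 1, Lhb, and DESeq2 called 0 after adjustment. Growth hormone, Gh, was at 196599 ± 49815 CPM in controls and 168913 ± 35893 CPM with anti-CD115 (SD, n = 4 each; log2 -0.20, SE 0.13, adjusted p = 0.648). Prolactin, Prl, had a log2 change of -0.11 (SE 0.17), proopiomelanocortin, Pomc, of 0.29 (SE 0.20), and the common alpha subunit Cga of 0.07 (SE 0.14). The beta subunits Fshb (0.01, SE 0.15) and Tshb (0.09, SE 0.17) were within their errors of 0. The luteinising hormone subunit Lhb went from 909 ± 213 to 647 ± 340 CPM (SD, n = 4 each; log2 -0.58, SE 0.20, edgeR adjusted p = 0.345), and without anti-CD115 replicate 3, the treated library with the highest Lhb, it passed (-0.84, adjusted p = 0.0112). It passed also without the low-count filter (adjusted p = 0.00134). The list as a whole had a median log2 change of 0.01 and a mean of -0.06, with camera pointing down (adjusted p = 0.547; adjusted p = 0.778 with an estimated correlation). The direction of Prl and of the list was upward without either female library: Prl gave 0.11 without isotype control replicate 1 and 0.10 without anti-CD115 replicate 1, and the list gave camera adjusted p of 0.334 and 0.319. Small values turned sign likewise for Cga without isotype control replicate 2 (-0.00193) or anti-CD115 replicate 3 (-0.01), for Tshb without isotype control replicate 2 (-0.04) or anti-CD115 replicate 2 (-0.08), and for Fshb without isotype control replicate 3 or 4 (-0.08 and -0.02) or anti-CD115 replicate 3 or 4 (-0.04 in each case). In simulated counts the same test recovered 33.3% of genes changed 1.5-fold, so changes of that size were often not detectable with these libraries.

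**Figure D3:**
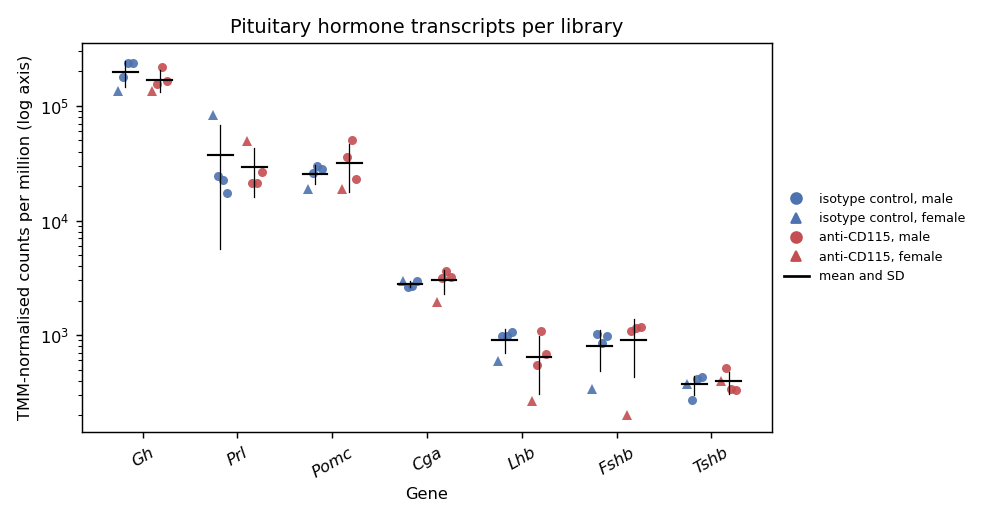
TMM-normalised CPM (log axis) of the 7 pituitary hormone genes in each library, with isotype control in blue and anti-CD115 in red, males as circles and females as triangles, and the mean and SD of each group of 4 in black. Prl is highest in the females of both groups and Fshb lowest in them; none of the 7 differed between treatments at an adjusted p below 0.05.

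Lists of endocrine cell types held no gene that passed over all genes. A camera call only at the preset correlation, here or for other lists, is weak evidence of a treatment effect. Splits with 2 treated and 2 control libraries on each side called 4 to 15 lists, the macrophage and hormone lists aside. Members also varied together (estimated correlation 0.131 for corticotroph and 0.730 for endothelial markers). Values on the same side of 0 are thus not independent. Thyrotroph markers were higher as a list, with 0 of 4 rising over all genes and 2 adjusted over the list alone, Trhr, the receptor of thyrotropin-releasing hormone (log2 0.57, edgeR adjusted p = 0.0657), and Gata2 (0.37, 0.199), while Dio2 gave 0.43. The thyrotroph list had a median log2 change of 0.40 (camera adjusted p = 7.83e-04; adjusted p = 0.149 with an estimated correlation). Trhr passed without isotype control replicate 4 (0.0489) or anti-CD115 replicate 3 (0.0492). DESeq2 called it too (0.00268), and without the low-count filter Trhr (0.00444), Gata2 (0.0270) and Dio2 (0.0452) passed. Corticotroph markers were higher as a list, with all 7 values above 0 and none called over all genes or over the list alone (median log2 0.28, camera adjusted p = 0.0121; adjusted p = 0.269 with an estimated correlation); Gpc5 gave 0.66, Pcsk1 0.17 and Neurod1 0.39. This call ended without isotype control replicate 1 (0.113) or anti-CD115 replicate 1 (0.118). Males only, nearly the same comparison as leaving out either female, gave 0.122 for the corticotroph list. Somatotroph (0 of 5, among them Dlk1 at 0.27; median -0.04, camera pointing up, adjusted p = 0.945), lactotroph (0 of 5, among them Edil3 at -0.15 and Esr1 at -0.11; median -0.11, down, 0.455) and melanotroph markers (0 of 5, among them Pax7 at 0.29 and Pcsk2 at 0.27; median 0.24, up, 0.0941) had no call over all genes or adjusted over the list alone. Gonadotroph markers had 0 of 8 called over all genes and 1 rise adjusted over the list alone, Nr0b1, which encodes DAX1 (0.82, edgeR adjusted p = 0.244; median of the list 0.08, up, camera adjusted p = 0.239). The gonadotroph list passed upward without isotype control replicate 1 (0.00159) or anti-CD115 replicate 1 (0.00143), and Nr0b1 passed without anti-CD115 replicate 3 (0.0237). In males only the gonadotroph list passed (0.00167), and Nr0b1 passed with DESeq2 (0.0318) and without the low-count filter (0.00312). Melanotroph markers passed without isotype control replicate 2 (0.0219) or anti-CD115 replicate 4 (7.86e-04). They passed without the low-count filter (0.0314). The somatotroph list pointed down without isotype control replicate 2 or 3 (0.682 and 0.890) or anti-CD115 replicate 4 (0.977), and the lactotroph list pointed up without isotype control replicate 1 (0.937) or anti-CD115 replicate 1 (0.935).

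Camera also called genes of hormone secretion and of pituitary lineage higher, without any member past the threshold over all genes. Secretory granule genes had 2 rises of 17 adjusted over the list alone, with 17 in neither direction over all genes (median log2 0.08, camera adjusted p = 0.00205; adjusted p = 0.161 with an estimated correlation); secretogranin 2, Scg2, gave 0.34 (edgeR adjusted p = 0.0731), chromogranin A, Chga, 0.43 (0.222) and Rab3b 0.23 (0.383). Scg2 passed with DESeq2 (0.00173), limma-voom (0.0496) and without the low-count filter (0.0180), and Chga with DESeq2 (0.0336) and without that filter (0.00347). Pituitary lineage transcription factors had 0 of 19 called in either way of adjusting, with 16 values above 0 (median log2 0.11, camera adjusted p = 0.00323; adjusted p = 0.355 with an estimated correlation), among them Gata2 (0.37) and Isl1 (0.39). Calcium handling genes had 0 of 27 called and 1 rise adjusted over the list alone (median log2 0.08, camera adjusted p = 0.0290; adjusted p = 0.565 with an estimated correlation), with Atp2a3 at 0.49 (edgeR adjusted p = 0.0915), Cacna1a at -0.33 and Itpr3 at 0.48. The calcium list did not pass without isotype control replicate 1 or 3 (0.134 and 0.304) or without anti-CD115 replicate 1, 3 or 4 (0.138, 0.0518 and 0.0713). Nor did it with log2(FPKM + 1) (0.0642), log2(FPKM + 0.1) (0.0740) or males only (0.146). Atp2a3 passed with DESeq2 (0.00904) and without the low-count filter (0.0256), as did Itpr3 without that filter (0.0156). Pituitary receptors had 0 of 27 called and 1 rise adjusted over the list alone (median log2 0.11, up, camera adjusted p = 0.0577), and passed without isotype control replicate 2 or 4 (0.0239 and 0.0387) or anti-CD115 replicate 3 (0.0299). They passed without the low-count filter (0.0190) and with unfiltered FPKM (0.0302). Stem and folliculostellate markers had 0 of 12 called (median 0.10, up, 0.114) and passed without isotype control replicate 2 (0.0277) or anti-CD115 replicate 4 (0.0392) and with unfiltered FPKM (0.0439).

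Vascular, neural and heat shock lists pointed up as well, again with 0 members called over all genes. All 10 endothelial markers had values above 0 (median log2 0.27, camera adjusted p = 6.79e-05; adjusted p = 0.359 with an estimated correlation; 0 adjusted over the list alone), among them Tek (0.41), Cldn5 (0.68) and Cdh5 (0.34). Mural and fibroblast markers, with 0 of 11 called in either way of adjusting, had a median log2 change of 0.23 (camera adjusted p = 0.0458; adjusted p = 0.5999 with an estimated correlation), with Cspg4 at 0.45, Tagln at 0.65 and Rgs5 at 0.26. Their call ended without isotype control replicate 1 or 4 (0.0818 and 0.481) or anti-CD115 replicate 1 or 2 (0.0819 and 0.324). It also ended with DESeq2 (0.0547), limma-voom (0.0748), the stricter filter (0.0528), log2(FPKM + 1) (0.377), log2(FPKM + 0.1) (0.402), unfiltered FPKM (0.0714) and males only (0.0861). Smooth muscle transcripts stood apart in anti-CD115 replicate 2, with Acta2 at 44.1 CPM and Myh11 at 22.1 CPM, against at most 14.7 and 7.44 CPM elsewhere. Tek passed without the low-count filter (0.0420). Heat shock genes had 3 rises of 8 adjusted over the list alone and 0 over all genes (median log2 0.23, camera adjusted p = 6.29e-04; adjusted p = 0.269 with an estimated correlation), with Hsph1 at 0.40, Hspa8 at 0.37 and Hspa1b at 0.74. Hsph1 and Hspa8 passed with DESeq2 (0.0136 and 0.0263) and without the low-count filter (0.00667 and 0.0135). Neuron and brain markers had 2 rises of 11 adjusted over the list alone and 0 over all genes (median log2 0.50, camera adjusted p = 0.00323; adjusted p = 0.297 with an estimated correlation), with Aqp4 at 0.61 (edgeR adjusted p = 0.0624), Nefm at 0.45 (0.0776) and Nefl at 0.66 (0.379). Single libraries carried part of this: Camk2a stood at 220 CPM in anti-CD115 replicate 1 and the myelin gene Mbp at 163 CPM in anti-CD115 replicate 3, against at most 27.8 and 73.5 CPM in the other libraries. The neuron and brain call ended without isotype control replicate 1 (0.162), anti-CD115 replicate 1 (0.156) or anti-CD115 replicate 3 (0.137), while Aqp4 passed without isotype control replicate 2 (0.0382). Males only, nearly the same comparison as leaving out either female, gave 0.165 for the neuron and brain list. Aqp4 and Nefm passed with DESeq2 (0.00173 and 0.00760) and, with Nefl, without the low-count filter (0.00159, 0.0178 and 0.0396). Without both of these anti-CD115 libraries, an alternative added after the data were seen, the list pointed down (camera adjusted p = 0.771) and 97 genes were called in all, with 94 falls and 3 rises.

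The other lists had no member called over all genes or adjusted over the list alone, and camera did not pass. They were pituicyte markers (6 measured, median log2 0.14, up, camera adjusted p = 0.239), extracellular matrix (14, median -0.00137, mean 0.00519, up, 0.126), immediate early genes (14, median 0.21, up, 0.218), cell cycle genes (17, median -0.18, down, 0.218), unfolded protein response genes (10, median -0.03, down, 0.469), red blood cell markers (6, median -0.02, mean 0.15, up, 0.613), skeletal muscle (3, median -0.10, down, 0.620) and mitochondrially encoded genes (13, median 0.01, mean -0.01, down, 0.722). Of the cartilage and bone list 2 members were expressed, too few for camera, and neither passed. Some passed when 1 library was left out. Pituicyte markers did so without isotype control replicate 2 (8.53e-04), extracellular matrix without isotype control replicate 3 (3.17e-04) or anti-CD115 replicate 3 (0.0147), and immediate early genes without isotype control replicate 4 (0.00740), anti-CD115 replicate 2 (0.00693) or anti-CD115 replicate 3 (0.0346). Cell cycle genes passed downward without isotype control replicate 2 or 3 (0.00319 and 0.00553) or anti-CD115 replicate 2 or 4 (0.0463 and 0.0201), and pointed up without isotype control replicate 1 or 4 (0.162 and 0.586) or anti-CD115 replicate 1 (0.158). Uncalled directions also turned for unfolded protein response genes without isotype control replicate 1 (0.664) or anti-CD115 replicate 1 (0.664), and for red blood cell markers without isotype control replicate 2 (0.674) or anti-CD115 replicate 4 (0.670). They turned for pituicyte markers without isotype control replicate 4 (0.533), for immediate early genes without anti-CD115 replicate 4 (0.918), and for mitochondrially encoded genes without isotype control replicate 4 (0.828) or anti-CD115 replicate 2 (0.324).

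The 7 genes that rose were the cGMP-dependent protein kinase Prkg1 (log2 1.02, SE 0.18), the AMPA receptor auxiliary proteins Shisa9 (0.60, SE 0.12) and Cnih2 (0.50, SE 0.09), Fam196a (0.60, SE 0.10), the tandem-pore potassium channel Kcnk9 (0.51, SE 0.09), the kinase Ptk2b (0.45, SE 0.09) and the actin-binding Synpo2 (0.43, SE 0.08). Prkg1 went from 4.27 ± 0.874 to 8.70 ± 1.27 CPM (SD, n = 4 each; edgeR adjusted p = 0.0262) and Kcnk9 from 56.6 ± 4.19 to 80.8 ± 6.65 CPM (0.0207). None of the 7 was on a gene list, and each was higher in all 3 treated males than in all 3 control males. For each of the 7, leaving out 1 library ended the call for at least 4 and up to all 8 of the libraries, with adjusted p from 0.0565 to 0.225 where it ended. No rise was called without anti-CD115 replicate 2, and 2 were called without anti-CD115 replicate 4. Unfiltered FPKM ended all 7 calls (0.0551 to 0.353), and the filtered FPKM settings ended those of Shisa9, Fam196a, Kcnk9, Ptk2b and Synpo2 (0.122 to 0.317). Males only ended those of Shisa9, Fam196a, Cnih2, Ptk2b and Synpo2 (0.0653 to 0.220), and no sex term those of Fam196a (0.433), Cnih2 (0.229) and Synpo2 (0.561). A replicate block ended those of Fam196a (0.05004), Kcnk9 (0.0558), Cnih2 (0.0876), Ptk2b (0.0851) and Synpo2 (0.0996). Limma-voom ended those of Shisa9 (0.0557), Ptk2b (0.0519) and Synpo2 (0.0598), and the stricter filter those of Shisa9 (0.0508) and Ptk2b (0.0582).

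The labels also give sex, and the sex term of the same model compared 2 females with 6 males. It called 87 genes, 49 higher and 38 lower in females, Xist and the Y-linked genes among them, with 1611 at an unadjusted p below 0.05. Prl was 2.97-fold higher in females (66676 ± 24370 CPM, SD, n = 2, against 22184 CPM in males; log2 1.57, edgeR adjusted p = 0.00470), and Fshb was 3.89-fold lower (269 ± 94.8 CPM, SD, n = 2, against 1047 CPM; log2 -1.96, adjusted p = 0.00192). Lhb had a log2 difference of -1.13 (adjusted p = 0.0968) and passed without anti-CD115 replicate 3 (-0.97, adjusted p = 0.0195). Among genes with a mean log2 CPM of at least 1, the largest differences upward in females were in the extracellular matrix protein reelin, Reln (3.00), the glutamate receptor Grm5 (2.44), Nhlh2 (2.02), Gucy2f (1.91) and the oestrogen-induced Greb1 (1.87). Downward they were in the dopamine receptor Drd4, Gpr101 (-3.72), Serpina3c (-3.58), Cabp7 (-2.69) and lipocalin 2, Lcn2 (-2.03). Drd4 had 1 count in both females together, and its pooled male to female ratio of 178 had a 95% counting interval of 31.7 to 7025. Reln rested on the control female (42.1 CPM, against 6.31 CPM in the anti-CD115 female and at most 3.64 CPM in males): without isotype control replicate 1 its log2 difference was 0.87 (adjusted p = 0.540). Without that library Nhlh2 (log2 1.42, 0.122), Gucy2f (1.10, 0.609), Greb1 (1.32, 0.338) and Cabp7 (-1.92, 0.149) did not pass either, and Gpr101 and Serpina3c gave -3.12 and -2.97. Without anti-CD115 replicate 1 the values were larger for Reln (4.27), Gucy2f (2.57), Gpr101 (-4.91), Serpina3c (-4.89) and Cabp7 (-4.05). Reln also missed the threshold without any 1 of the males (0.0601 to 0.103), Gucy2f without isotype control replicate 2 or 4 or anti-CD115 replicate 3 (0.0721, 0.0786 and 0.0792), and Cabp7 without isotype control replicate 2 or 4 or anti-CD115 replicate 3 or 4 (0.0528, 0.0526, 0.0521 and 0.0649). With unfiltered FPKM the calls ended for Prl (0.879), Reln (0.520), Nhlh2 (0.125), Gucy2f (0.248), Greb1 (0.253), Drd4 (0.0908), Gpr101 (0.0686), Serpina3c (0.0849) and Cabp7 (0.144). Limma-voom ended those of Reln (0.0878) and Cabp7 (0.0578), and log2(FPKM + 1) and log2(FPKM + 0.1) that of Gucy2f (0.0764 and 0.140). Lhb passed with DESeq2 (3.72e-05) and without the low-count filter (1.11e-07). The count of genes called for sex was 46 without isotype control replicate 4, 53, 50 and 51 without anti-CD115 replicate 1, 3 and 4, 336 with DESeq2 and 601 without the low-count filter.

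Whether the treatment effect differed between the sexes was tested with an interaction term, with 1 female in each group. It called 7 genes, 5 with a higher and 2 with a lower value in the female pair (568 at an unadjusted p below 0.05). A pair of single libraries cannot part a sex difference from a library that stands apart. The smallest p belonged to Camk2a, a kinase abundant in forebrain neurons (log2 3.67, SE 0.27, edgeR adjusted p = 0.00188), Stum (4.57), Reln (-3.40), the postsynaptic dendrin, Ddn (4.80), and Indian hedgehog, Ihh (-4.04). Camk2a was at 220 CPM in the anti-CD115 female, 21.6 CPM in the control female and 20.6 ± 3.70 CPM in males (SD, n = 6). Nrgn (3.01) and Jph4 (2.62), named after their values were seen, had the same pattern. Leaving out 1 male left between 2 and 6 calls: 2 without isotype control replicate 2, anti-CD115 replicate 3 or anti-CD115 replicate 4 and 4 without isotype control replicate 4. Camk2a and Stum kept their calls in each of these fits. Reln and Ddn lost theirs without isotype control replicate 2 (0.0543 and 0.0784), anti-CD115 replicate 3 (0.0658 and 0.145) or anti-CD115 replicate 4 (0.0660 and 0.0608). Ihh did without isotype control replicate 2 or 4 (0.0967 and 0.0678) or anti-CD115 replicate 3 or 4 (0.145 and 0.153), and Nrgn and Jph4 without any 1 male (0.0543 to 0.153). Ihh did so with limma-voom (0.118), log2(FPKM + 1) (0.127), log2(FPKM + 0.1) (0.103) and unfiltered FPKM (0.0507). Log2(FPKM + 0.1) ended the calls of Ddn (0.129), Nrgn (0.0829) and Jph4 (0.582), and log2(FPKM + 1) that of Jph4 (0.0566). DESeq2 called 42 genes for the interaction, and edgeR without the low-count filter 168.

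**Figure D4:**
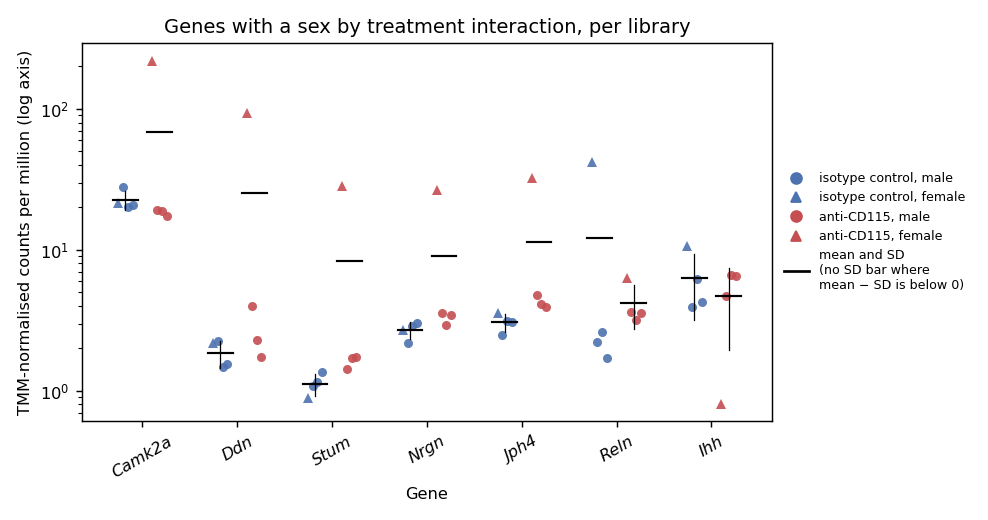
TMM-normalised CPM (log axis) of the 7 genes with a sex by treatment interaction in each library, with isotype control in blue and anti-CD115 in red, males as circles and females as triangles, the mean in black and the SD where the mean minus SD lies above 0. Camk2a stands at 220 CPM in the anti-CD115 female and at most at 27.8 CPM in the other libraries.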

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

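The tests of oligodendrocyte transcripts and of a female response below were chosen only after the result was seen; the test of further forebrain markers was set out before its values were known. A sample far from the other 3 of its group was sought in 234 groups of 4, and 25 were found; chance picks out about 1 in 20 groups. Of the 25, 13 lay in genes named for a sex difference or an interaction, all of them in replicate 1 (8 with anti-CD115 and 5 in the control). Replicate 1 was the only female of each group, so these stood apart by the way the genes were chosen. In all other genes 12 were found in 202 groups, about the 10.1 that chance gives.

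Several far values followed sex, since replicate 1 was the female of each group. Prl stood at 83908 CPM in isotype control replicate 1, against 17221 to 24569 CPM in the control males, and Fshb at 202 CPM in anti-CD115 replicate 1, against 1079.8 to 1178 CPM. Females stood above the males of their group in Reln (42.1 CPM in the control and 6.31 CPM in the anti-CD115 female), Grm5 (5.97 and 7.44 CPM) and Nhlh2 (22.4 and 11.9 CPM). Gucy2f (28.7 CPM), Greb1 (32.6 CPM) and Synpo2 (37.6 CPM, against 21.04 to 21.66 CPM) met the criterion in the control female only, although the anti-CD115 female also lay above the treated males (19.4, 10.14 and 43.9 CPM). In the anti-CD115 female P2ry12 was high at 2.46 CPM and Hsph1 low at 166 CPM, against 242 to 246 CPM in the treated males.

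The other far values lay in single male libraries. Fcrls was high in isotype control replicate 3 (12.1 CPM, against 6.60 to 7.23 CPM). In isotype control replicate 4 Zbtb46 (4.09 CPM) and Cspg4 (2.48 CPM) were low. H2-Aa (16.6 CPM) and Tek (33.4 CPM) were high in anti-CD115 replicate 4, Gusb was low in anti-CD115 replicate 2 (33.4 CPM, against 35.0 CPM), and Isl1 was low in anti-CD115 replicate 3 (12.7 CPM, against 14.3 to 14.5 CPM). Gusb, Isl1 and Tek (others 30.2 to 30.5 CPM) stood out mainly because the other 3 values lay close together. Fcrls and Cspg4 (others 4.16 to 4.30 CPM) lay further from the rest.

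With 1 female in each treatment group, the interaction test cannot tell a sex difference from single libraries that stand apart. Its 7 calls had log2 values of 3.67 (Camk2a), 4.57 (Stum), -3.40 (Reln), 4.80 (Ddn), -4.04 (Ihh), 3.01 (Nrgn) and 2.62 (Jph4). Of these, 5 were transcripts at their highest in the anti-CD115 female: Camk2a at 220.2 CPM, Stum at 28.3 CPM, Ddn at 93.6 CPM, Nrgn at 26.4 CPM and Jph4 at 32.5 CPM.

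These 5 could come from RNA of forebrain neurons in that library. Of 13 further forebrain markers detected, 11 were highest in it, with a median log2 excess of 0.949 over the mean of the other 7 libraries, just short of the bound of 1 set beforehand, so the test did not decide. Brain tissue with its oligodendrocytes was not shown either: 0 of 6 oligodendrocyte markers were highest there (median log2 excess 0.258). A response to the antibody in females only stays open, since there was 1 anti-CD115 female library.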

How the results depend on the processing

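With 4 animals per group, 1 of them female, and an unknown number of litters, small changes were often beyond reach, and litter may coincide with treatment. Of 48 named genes called for treatment, 21 kept their call in every alternative that measured them and 26 when each library was left out; 0 of the 7 rises did. Weakly expressed genes were not measured in the filtered FPKM settings. Of the 19 lists called, 2 kept the call in every alternative that tested them, and besides the hormone list 11 of 19 uncalled lists were called in some alternative. The cause of a difference was not tested unless fewer genes or fewer libraries are named.

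For genes changed by anti-CD115 the counts of all, higher and lower genes were 154, 7 and 147. DESeq2 gave 268, 52 and 216, and no low-count filter gave 487, 134 and 353, with 32025 genes tested; only 43 of the 487 lay outside the filter, so most of the increase was in genes already tested. The deposited FPKM values gave 33, 1 and 32 as log2(FPKM + 1), 29, 1 and 28 as log2(FPKM + 0.1), and 67, 1 and 66 without a filter, where the filtered fits tested fewer genes. Males only, with fewer libraries, gave 3 higher genes. Leaving out 1 library gave 89 to 120 changed genes, 0 to 7 higher and 87 to 117 lower. Treating equal replicate numbers as a block gave 4 higher genes and 118 in all, and the somatotroph list then pointed down (camera adjusted p = 0.927). Deviations of equal numbers correlated at 0.417, -0.0962, 0.0652 and 0.306. The highest correlations with another number were -0.0669, 0.0644, 0.182 and 0.230. Replicate 1 was the female of each group, and the other numbers went both ways. Whether the numbers pair the animals is thus not settled. With the estimated inter-gene correlation 1 other gene list was called in place of 18; leaving out 1 library gave 15 to 22, and the macrophage list ran from 1.98e-181 to 2.96e-81.

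Directions that turned were mostly those of uncalled lists, given as camera adjusted p. The somatotroph list turned with limma-voom (0.973), log2(FPKM + 1) (0.943), log2(FPKM + 0.1) (0.9504) and no sex term (0.999). The skeletal muscle list turned without a low-count filter (0.954) and with unfiltered FPKM (0.979), as did the neutrophil list with unfiltered FPKM (0.979). With the stricter filter, log2(FPKM + 1) and log2(FPKM + 0.1) the red blood cell list gave 0.844, 0.839 and 0.796, and the CSF ligand list 0.419, 0.482 and 0.411. On the same FPKM scales the monocyte list gave 0.849 and 0.907, and the purinergic list 0.223 and 0.172. In males only Prl had a log2 change of 0.11, and the hormone list (0.331), lactotroph (0.934), cell cycle (0.165) and unfolded protein response lists (0.677) turned.

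Leaving out 1 library, log2 changes ran from -0.25 to 0.11 for Prl, -0.0124 to 0.285 for Cga, -0.0802 to 0.175 for Tshb, -0.0840 to 0.258 for Fshb and -0.0439 to 0.553 for Ccl2. Adjusted p ran from 0.0518 to 0.823 for the hormone list, 0.200 to 0.937 for lactotroph, 0.502 to 0.977 for somatotroph, 0.00319 to 0.586 for cell cycle, 0.0869 to 0.820 for unfolded protein response, 0.165 to 0.962 for red blood cell and 0.166 to 0.925 for neutrophil lists. It ran from 0.268 to 0.748 for CSF ligands, 8.53e-04 to 0.533 for pituicyte, 0.136 to 0.828 for mitochondrially encoded and 0.00693 to 0.918 for immediate early genes.

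Leaving out anti-CD115 replicates 1 and 3, chosen after seeing the data, gave 97 changed genes, 3 higher and 94 lower. Prl then had a log2 change of 0.16, and the somatotroph, lactotroph and melanotroph lists (each 0.987), the neuron and brain list (0.771) and the cell cycle list (0.0224, upward) turned. Lhb passed (log2 -0.71, adjusted p = 0.0436). The interferon (0.181), secretory granule (0.0696), corticotroph (0.168) and calcium handling lists (0.242) did not pass, while gonadotroph (0.0127), red blood cell (0.00456) and extracellular matrix lists (0.00697) did.

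For genes differing between sexes 87 became 336 with DESeq2, 601 without a low-count filter, 35, 38 and 32 with the FPKM settings log2(FPKM + 1), log2(FPKM + 0.1) and no filter, and 46 to 92 leaving out 1 library. For genes whose treatment effect differs between sexes 7 became 42 with DESeq2, 168 without a low-count filter, 1 with log2(FPKM + 0.1), 654 with unfiltered FPKM, and 2 to 6 leaving out 1 male.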

Other observations

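The tests of class II transcripts and of the rises below were chosen only after the result was seen; the splits of the libraries were set out before. Of the 147 fallen genes, 108 were on no list. The 10 most abundant protein-coding ones, picked after their values were seen, were Slc39a14 (log2 -0.67), Cdkn1a (-0.95), Unc93b1 (-0.89), Lcp1 (-0.99), Ctsc (-1.06), Ctsh (-0.90), Cybb (-2.65), Plek (-0.61), Pld4 (-2.82) and Slco2b1 (-1.50). Leaving out 1 library ended the call of Slc39a14 for 3 libraries (0.0531 to 0.0822), Cdkn1a for 7 (0.0650 to 0.156), Ctsh for 5 (0.0519 to 0.0974), Plek for 8 (0.0561 to 0.153) and Slco2b1 for 5 (0.0611 to 0.116). Other settings also ended the calls of these and that of Lcp1 (0.0785 with log2(FPKM + 1), 0.0953 with log2(FPKM + 0.1) and 0.156 with unfiltered FPKM).

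Some single libraries stood apart in transcripts picked out after their values were seen, and whether other tissue brought them was not tested. Isotype control replicate 3 had Ptgds at 819 CPM, against at most 59.7 CPM elsewhere, together with Fmod (47.8 CPM), Slc13a4 (21.1 CPM), Slc6a13 (13.7 CPM) and Slc22a8 (11.6 CPM), genes expressed in the meninges. Anti-CD115 replicate 3 had the myelin transcripts Mbp (163 CPM) and Mobp (23.1 CPM) and the astrocyte gene Gfap (24.2 CPM), against at most 73.5, 4.39 and 11.3 CPM. Genes more than 2-fold above every other library numbered 57 in anti-CD115 replicate 1, 29 in isotype control replicate 3 and 22 in isotype control replicate 1. Siglech and P2ry13, on different chromosomes, had identical deposited counts in each anti-CD115 library and different counts in the controls.

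All 35 splits of the 8 libraries into 4 and 4 were fitted in the same way. For genes changed by anti-CD115, 1 split of 35, the real one, reached 154, and the highest other gave 0. For genes lower with anti-CD115, 1 split reached 147 and the highest other gave 0, and for the macrophage marker list 1 split reached 1.07e-113 and the next gave 1.28e-33. No other split matched the real one for these. A share of 1 in 35 is the smallest that 35 splits can give, and the other splits mix treated and control libraries. The splits alone therefore do not exclude chance. For the pituitary hormone list 26 of 35 splits gave a camera p as small as 0.477, and the smallest was 2.10e-04. For other gene lists 2 of 35 gave as many as 18, and the highest other gave 19. For both of these the real split did not stand out.

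MHC class II transcripts fell less than macrophage markers. The log2 ratio of class II genes to macrophage markers was 2.49 ± 0.112 in controls and 3.20 ± 0.467 with anti-CD115 (SD, n = 4 each), a difference of 0.701 (exact permutation p = 0.0286, the smallest possible). This restates the smaller fall and is no separate evidence for it. A loss of 1 pool of cells with fixed levels of both would have left the ratio unchanged only if no other cells carried either set. Whether other cells did was not settled, so the ratio does not exclude such a loss. Most of the difference lay in anti-CD115 replicates 2 and 4 (3.74 and 3.43), while replicates 1 and 3 (2.86 and 2.76) were close to the highest control (2.65). Replicates 1 and 3 were also the treated libraries that stood apart in brain-type transcripts. They kept more of the macrophage markers, with mean log2 levels of 1.49 and 1.58, against 0.446 and 0.984 in replicates 2 and 4. Remaining class II transcripts could come from dendritic and B cells that stayed: 5 of their measured markers had a median log2 change of 0.0925, but only 2 reached 1 CPM, and this set left out Itgax (-2.20) and Ighm (-1.36), which fell, so it decides nothing. Lower class II expression in surviving cells was not tested.

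The 7 rises might reflect a larger share of all other RNA. The 1068 CPM lost by the fallen genes would raise other genes by log2 0.00154 only. This sum covers the 147 called falls alone and leaves out lost transcripts of genes that were not called. It therefore understates the RNA lost. A larger share would, however, raise all other genes alike, and TMM scaling takes out a shift common to most genes. The median log2 change over the 17723 genes tested was 0.00406, against 0.433 to 1.02 for the 7 rises. This argues against a shared shift as the source of the 7 rises. Brain RNA in anti-CD115 replicates 1 and 3 might also have played a part. Without both libraries the median log2 change was 0.605, against 0.513 with all. Ptk2b dropped from 0.448 to 0.332, and the others were larger. The 7 genes were called in part on the libraries kept, so this is no independent test and does not decide. None of the 7 passed without both libraries (edgeR adjusted p 0.0684 to 0.366), with fewer libraries. Whether the rises are a response to the loss of macrophages or to litter, or come from brain RNA, stays open.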
